A study of Mus musculus with 10 samples.

How the data were processed

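RNA was sequenced from 10 prostate orthograft tumours grown in male CD-1 Nude mice, which lack a normal thymus. Each mouse received cells of 1 of 3 mouse prostate cancer lines in an anterior prostate lobe. The line P1 came from a prostate tumour of a donor of 14 months and gave 3 tumours. The lines CP1 and CP2 came from prostate tumours with a deletion in Ctnnb1 that stabilises beta-catenin, taken from donors of 6 and 8 months, and gave 3 and 4 tumours. The genotypes of P1 and the CP lines differ in more than this deletion. Line, genotype and donor age change together, so no comparison separates them. The labels do not tie each library to its own animal, and p-values therefore measure the spread between these samples, part of which may be technical. CP2 replicate 1 has a title that names CP1, while its tissue and source labels name CP2. It was kept in CP2, as those labels say, and its mean correlation of log2 CPM across genes was 0.984 with the other CP2 tumours, 0.912 with CP1 and 0.842 with P1.

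The deposited values are whole-number counts of reads per Ensembl gene, 1 file per tumour, not normalised. Per the submitters' processing notes the tools were FastQC 0.11.4, TopHat2 2.1.0, Bowtie2 2.2.6.0, HTSeq 0.6.0, R 3.2.3 and DESeq2 1.14.1, with the genome build GRCm38.p3. The notes give no order, parameters or annotation. Whether the libraries mark strand, and whether counting used strand, is not given in the sources used here, so genes that overlap or lie antisense to another gene are uncertain. The same holds for near-identical copies that counting could split, such as Svs3a and Svs3b, the granzyme cluster from Gzmb to Gzmg, and the H2 class I genes. Each file listed 47069 gene IDs. Of these, 46574 matched GENCODE M21 (GRCm38), which gave the symbols and coordinates, and 495 did not and have no symbol here. No line of the files names something other than a gene. Totals ranged from 18800912 to 37180721 counts per tumour.

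Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes with low counts were removed with filterByExpr at its minimum count of 10 and minimum total of 15, which left 17644 genes, and libraries were scaled with TMM factors. All 10 tumours entered a single quasi-likelihood fit with a mean per line, so the 3 lines share an estimate of the spread. The contrasts were CP1 versus P1, CP2 versus P1, CP2 versus CP1, and the mean of CP1 and CP2 versus P1. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and every adjusted p of a gene below comes from this test unless another is named. CPM use TMM-scaled library sizes and are given as mean ± SD, and log2 fold changes carry their SE. The SE is the log2 fold change divided by the square root of the F statistic. For a gene with 0 counts in a group, the fold is given as a lower bound, from counts summed over each group and scaled by its summed library sizes, with a floor of 3 counts over the group. For 1 to 3 counts it is the ratio of summed counts with an exact 95% binomial interval. Floors and intervals cover counting error only. Fold changes for the mean of CP1 and CP2, and those under alternatives, stay as fitted. At 0 counts they depend on the prior count.

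The 28 gene lists, the test designs, the rule for named genes and most alternatives were fixed before the data were examined. List tests used camera with a preset inter-gene correlation of 0.01, adjusted over the 28 lists within a contrast. No list was called in any contrast when the correlation was estimated, and adjusted p-values with an estimated correlation stand beside the calls. Over the 112 list results, the median, the mean and the test differed in sign in 15, none of them called. 3 further marker lists, for urothelium (13 genes, 4 of them in a fixed list), for granzymes and perforin (7 genes, 2 in a fixed list) and for intestinal epithelium (16 genes, 0 in a fixed list), were written after the data were seen.

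The rule for named genes took 5 genes in every comparison, among them Ctnnb1, Myc and Wnt5a. It added per comparison the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and no overlap of the tumours' values. Per list it added up to 2 members in each direction and the most highly expressed member not called. The text names fewer than the rule gives, and it gives no fold change for the list members selected as not called. The list members named with a fold change are thus called ones and no balanced draw from their lists. Axin2, Krt8, Cdh1, Mycn, Cdkn2a, Hnf4a, Cdx2 and Vil1 fall outside the rule and were chosen after their values were seen. A shorter selection was drawn up after values and alternatives had been seen, which left out Msmb, Gbp2 and Spink1, whose direction turned under an alternative, and 9 further genes, most of them near 0 counts in a group. These 12 genes were put back. Some items, namely part of the genotypes and 5 of the genes selected, including 2 of those taken in every comparison and 1 of the 12, are not reported here.

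The test was tried on simulated counts of 17288 genes with 200 changed in each CP line, 100 by 2-fold and 100 by 4-fold, and a list of 20 more raised 2-fold in CP1. For CP1 versus P1 it recovered 45% of 2-fold and 81% of 4-fold changes. Of its 136 calls, 126 were changed genes, 7 were genes of the raised list and 3 were false. For CP2 versus P1 it recovered 54% and 85%, and of 147 calls 139 were changed genes and 8 were false. Camera called a simulated changed list and did not call a random list. Simulated genes varied independently, whereas estimated correlations were 0.69 for the cell cycle list (CP1 versus P1) and 0.825 for smooth muscle (CP2 versus CP1). The trial therefore does not check the preset correlation of 0.01 on such lists. Far fewer genes were changed in it than were called in the data. Replicates were checked for duplicates with a chi-square test of their counts over genes. Its value per degree of freedom lay between 11.2 and 320.5 for the 12 pairs within a line, so every pair differed by more than sampling noise. It was 161 to 320.5 in P1, 47.1 to 68.5 in CP1 and 11.2 to 19.7 in CP2. Depth also enters these values, but the lines that share an estimate of the spread were not alike in it.

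Alternatives set beforehand were RLE size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a test against a 2-fold change, only the tumours of the lines compared, the title number as a replicate block, each tumour left out in turn, and for lists an estimated correlation, fry and RLE. Chosen after seeing the data were the removal of P1 replicates 1 and 2, the removal of CP1 replicates 2 and 3, the mean log2 CPM of the seminal vesicle list as a covariate, the removal of the seminal vesicle genes, and counts thinned to the smallest total. The P1 replicates are those with the most seminal vesicle transcripts, and the CP1 replicates those with the most urothelial and smooth muscle transcripts. Each of these removals leaves 1 tumour in its line, P1 replicate 3 or CP1 replicate 1. The spread then comes from the other lines alone. Calls and counts from these fits thus describe that 1 tumour and do not measure the spread within its line. The exon-level deletion of Ctnnb1 was not analysed here, since the counts are per gene.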

Results

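Transcript abundance was measured by RNA sequencing in prostate orthografts of the mouse lines P1 (n = 3), CP1 and CP2 (both with stabilised beta-catenin, n = 3 and n = 4). P1 libraries held 28050484 to 37180721 counts, CP1 libraries 25081535 to 30546426 and CP2 libraries 18800912 to 20638085. The lower CP2 depth gives less precision for rare transcripts there, since 3 counts in a library correspond to 0.137 to 0.154 CPM in CP2 and to 0.0924 to 0.109 CPM in P1. The first principal component of the 500 most variable genes held 68.4% of their variance and placed P1 apart from both CP lines. The second held 21.5% and placed CP1 apart from CP2. Transcripts of the seminal vesicle and secretory prostate list, called the seminal vesicle list for short, took 17.2%, 6.98% and 1.86% of the counts in P1 replicates 1, 2 and 3. They took 0.161% or less in every CP1 and CP2 tumour.

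**Figure D1:**
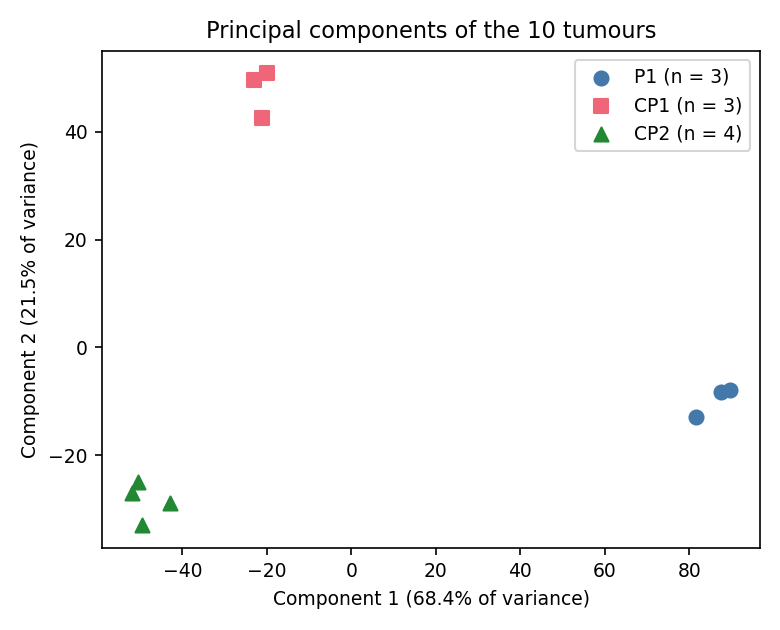
Each point is a tumour, placed by its first component (horizontal axis, 68.4% of variance) and second component (vertical axis, 21.5%) of the 500 most variable genes, with colour and shape for the line. P1, CP1 and CP2 tumours lie in 3 separate places.

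Ctnnb1, altered in the donor mice of CP1 and CP2, was examined first in each tumour. Ctnnb1 (ENSMUSG00000006932, GRCm38 chromosome 9: 120929216 to 120960507), which encodes beta-catenin, stood at 1798, 1953 and 1902 CPM in P1, at 1172, 917 and 1135 CPM in CP1, and at 1042, 1044, 937 and 1011 CPM in CP2. It was lower, at log2 -0.81 ± 0.12 in CP1 (adjusted p = 3.094e-04) and by -0.90 ± 0.11 in CP2 (adjusted p = 6.671e-05). CP2 minus CP1 was -0.09 ± 0.11 (adjusted p = 0.512). The fall in CP1 was -0.77 and not called with the seminal vesicle covariate (adjusted p = 0.0862). Gene counts do not check the deleted exon. Deletion of an exon that removes the phosphorylation sites acts on the protein's stability, which counts of RNA do not show.

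Myc and Wnt5a were likewise examined in every comparison. Myc (ENSMUSG00000022346, chromosome 15: 61985391 to 61990374) fell from 96.5 ± 17.2 CPM in P1 to 65.7 ± 8.20 in CP1 and 42.7 ± 2.19 in CP2, by -0.55 ± 0.13 (adjusted p = 0.0071) and -1.18 ± 0.12 (adjusted p = 3.314e-05). CP2 was lower than CP1 by -0.62 ± 0.12 (adjusted p = 0.0030). Wnt5a (ENSMUSG00000021994, chromosome 14: 28504750 to 28527448), a ligand best known for beta-catenin-independent signalling, rose from 22.5 ± 14.7 CPM in P1 to 1160 ± 183 in CP1 and 585 ± 39.2 in CP2. The rises were 5.68 ± 0.43 (adjusted p = 6.531e-06) and 4.70 ± 0.40 (adjusted p = 9.035e-06). CP2 stood below CP1, at log2 -0.99 ± 0.33 (adjusted p = 0.0331), and this call was lost when any 1 of the 7 CP1 and CP2 tumours was left out (0.0546 to 0.0971) and with no filter on low counts (0.0608). Removal of CP1 replicates 2 and 3 gave -1.23 for it (adjusted p = 0.102). The Myc fall in CP1 was then -0.57 and not called (adjusted p = 0.0557), nor was it with the seminal vesicle covariate (-0.71, adjusted p = 0.160).

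**Figure D2:**
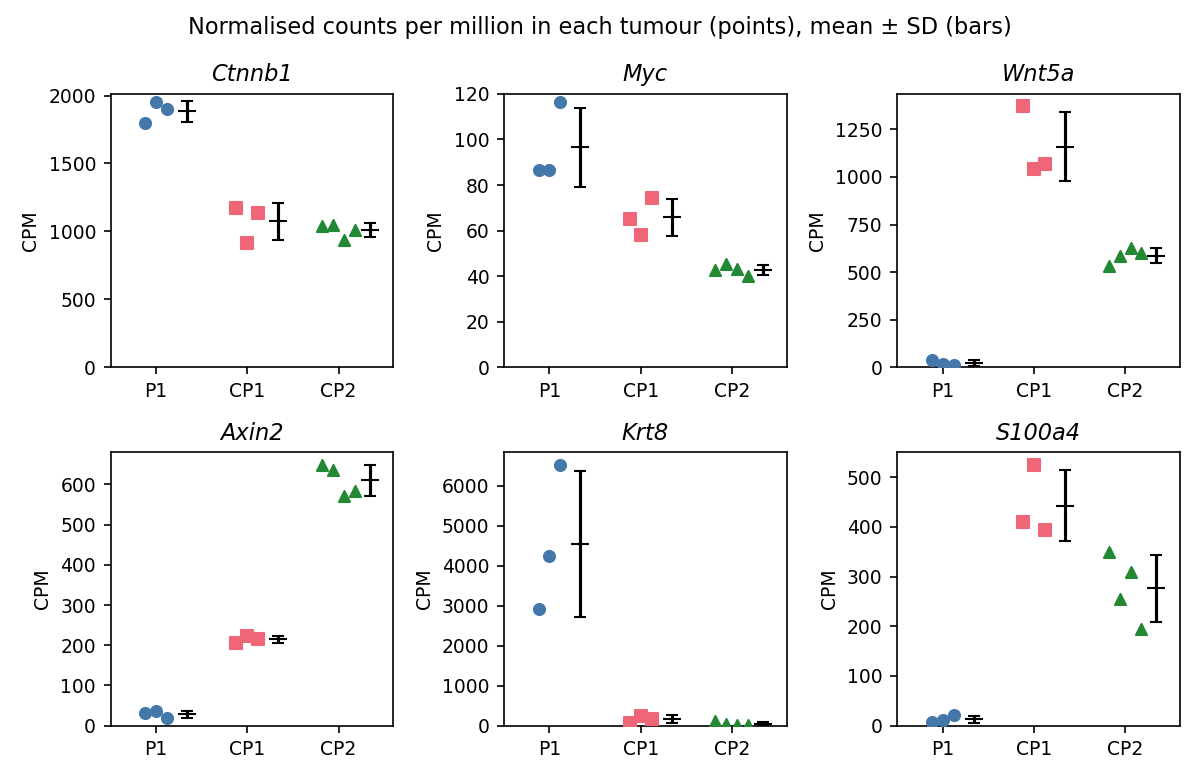
Each panel plots CPM (vertical axis, linear, from 0) of a gene in each tumour (points, by line) with the mean ± SD per line as a bar. Axin2 was lowest in P1 and highest in CP2, Ctnnb1, Myc and Krt8 were highest in P1, and Wnt5a and S100a4 were highest in CP1.

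The comparison of CP1 with P1 asks how a beta-catenin-stabilised line differs from P1. Of 17644 genes tested, 3955 were higher and 3951 lower in CP1, and 2661 changed by more than 2-fold in the test against a 2-fold change. Of the luminal epithelium list 13 of 20 genes fell and 1 rose. Of the epithelial-mesenchymal transition list 12 of 18 rose and 2 fell, and of the cell cycle list 18 of 25 rose and 0 fell. Falls were called for 13 of 24 interferon, 10 of 15 antigen presentation, 11 of 20 NF-kappaB and 12 of 17 lymphocyte genes, and rises for 4 NF-kappaB genes. Camera called these 7 lists at the preset correlation and 0 lists with an estimated correlation (adjusted p = 0.593 to 0.849 for the 7). The largest rises included Cyp11b1 (0.332 ± 0.255 to 209 ± 71.1 CPM, log2 9.26 ± 0.56, adjusted p = 2.148e-06), a steroid hydroxylase, and Cck (3.70 ± 2.78 to 986 ± 154 CPM, 8.05 ± 0.59, adjusted p = 5.181e-06), which encodes the peptide hormone cholecystokinin. Brinp3 rose by 7.90 ± 0.37, the sodium-calcium exchanger gene Slc24a2 by 7.93 ± 0.53 and Gpr37 by 8.21 ± 0.67 (adjusted p = 6.051e-07, 3.560e-06 and 1.076e-05). Upk3a, a uroplakin of the bladder lining, had 0.116 ± 0.122 CPM in P1 and 119 ± 121 in CP1, at 8.16, 249 and 99.1 CPM in CP1 replicates 1, 2 and 3 (log2 10.02 ± 1.54, adjusted p = 5.077e-04). Svs2, Svs4 and Pate4, secretory genes of the seminal vesicle, fell, at log2 -12.50 ± 2.80, -12.29 ± 2.70 and -12.19 ± 2.2 (adjusted p = 0.0049, 0.0044 and 0.0014). The calls were lost with CP1 replicates 2 and 3 removed, which leaves fewer samples. The values were then -12.48, -12.36 and -12.12 (adjusted p = 0.147, 0.125 and 0.0858). The seminal vesicle covariate ended them too (-2.70, -0.61 and -5.90, adjusted p = 0.660, 0.856 and 0.198), and that of Upk3a (1.99, adjusted p = 0.890). This covariate averages a list that holds Svs2, Svs4 and Pate4, and it follows the line closely. Loss of the Svs2, Svs4 and Pate4 calls therefore follows from its construction and does not test them.

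In the luminal epithelium list 13 of 20 genes fell and 1 rose in CP1, also when adjusted over the list alone (camera adjusted p = 1.209e-05; adjusted p = 0.593 with an estimated correlation). Prom1, a membrane protein of luminal progenitors, fell from 1728 ± 321 to 4.15 ± 1.47 CPM (log2 -8.70 ± 0.77, adjusted p = 1.724e-05) and Ppp1r1b from 422 ± 157 to 1.83 ± 0.451 CPM (-7.84 ± 0.66, adjusted p = 1.275e-05). The member that rose was Foxa1, a pioneer factor of prostate epithelium (1.12 ± 0.19, adjusted p = 0.0010). Of 18 genes of the epithelial-mesenchymal transition list 12 rose and 2 fell, and 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 4.396e-05; adjusted p = 0.593 with an estimated correlation). S100a4, a calcium-binding protein of motile cells, rose from 13.2 ± 7.00 to 443 ± 71.6 CPM (5.07 ± 0.40, adjusted p = 7.952e-06) and the transcription factor gene Snai1 from 11.8 ± 5.03 to 81.5 ± 17.3 CPM (2.79 ± 0.29, adjusted p = 4.574e-05). Twist1, of the same list, fell, at log2 -1.31 ± 0.16 (adjusted p = 1.100e-04). Transcripts of the fibroblast list took 0.573% to 1.09% of the counts in P1 tumours and 2.11% to 3.00% in CP1 tumours. In the cell cycle list 18 of 25 genes rose and 0 fell, or 18 and 1 adjusted over the list alone (camera adjusted p = 4.776e-05; adjusted p = 0.778 with an estimated correlation), among them the ribonucleotide reductase gene Rrm2 (2.91 ± 0.33, adjusted p = 6.860e-05) and E2f1 (1.36 ± 0.17, adjusted p = 1.166e-04). With P1 replicates 1 and 2 removed, 11 of 25 cell cycle genes rose and 1 fell, and the list was not called (0.0503). Calls of Foxa1 (0.91, adjusted p = 0.230) and E2f1 (1.12, adjusted p = 0.0715) were lost with the seminal vesicle covariate.

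The interferon, antigen presentation, NF-kappaB and lymphocyte lists were called lower in CP1, and the macrophage and neutrophil lists were not called (camera adjusted p = 0.444 and 0.595). In the interferon list 13 of 24 genes fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0045; adjusted p = 0.849 with an estimated correlation). The chemokine genes Cxcl9 and Cxcl10 fell, at log2 -6.94 ± 1.20 and -3.72 ± 0.69 (adjusted p = 0.0010 and 0.0016). In the antigen presentation list 10 of 15 fell and 0 rose, or 13 and 0 adjusted over the list alone (camera adjusted p = 0.0067; adjusted p = 0.778 with an estimated correlation), with the class II genes H2-DMb1 (-2.90 ± 0.44, adjusted p = 4.869e-04) and Cd74 (-2.09 ± 0.49, adjusted p = 0.0057). In the NF-kappaB list 11 of 20 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.0065; adjusted p = 0.593 with an estimated correlation). Cxcl5, a neutrophil chemokine gene, fell, at log2 -4.55 ± 0.37 (adjusted p = 1.005e-05) and Ccl20 from 3.96 ± 2.01 to 0.0471 ± 0.0816 CPM (adjusted p = 0.0017), whereas Ccl2 rose by 2.56 ± 0.40 (adjusted p = 5.767e-04). In the lymphocyte list 12 of 17 fell and 0 rose, or 13 and 0 adjusted over the list alone (camera adjusted p = 1.027e-04; adjusted p = 0.593 with an estimated correlation), with the granzyme genes Gzmb (-4.57 ± 0.41, adjusted p = 1.847e-05) and Gzma (-3.98 ± 0.69, adjusted p = 0.0010). With P1 replicates 1 and 2 removed, the interferon and antigen presentation lists (0.102 and 0.0655) and Cd74 (log2 -1.96, 0.0558) were not called. Falls were then called for 5 of 15 antigen presentation and 7 of 17 lymphocyte genes. With CP1 replicates 2 and 3 removed, the antigen presentation and NF-kappaB lists (0.0517 and 0.0769), Cxcl9 (log2 -6.74, 0.0606) and Cxcl10 (log2 -3.88, 0.0504) were not called. Of the genes, 6 of 24 interferon, 6 of 15 antigen presentation and 7 of 17 lymphocyte genes fell. The seminal vesicle covariate gave 1.61 for Ccl2 (adjusted p = 0.216), -2.09 for Cd74 (adjusted p = 0.224) and -9.43 for Ccl20 (adjusted p = 0.0546), none of them called.

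Targets of beta-catenin moved both ways in CP1. Of 25 measured, 9 rose and 12 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.898), its median being -0.43 and its mean 0.17 on the log2 scale. Removal of P1 replicates 1 and 2, or of CP1 replicates 2 and 3, left 9 higher and 8 lower. Axin2 (ENSMUSG00000000142, chromosome 11: 108920349 to 108950783), a feedback inhibitor of the pathway, rose from 28.6 ± 8.85 to 215 ± 8.96 CPM (log2 2.91 ± 0.21, adjusted p = 4.807e-06), and Apcdd1 from 16.3 ± 11 to 783 ± 244 CPM (5.58 ± 0.48, adjusted p = 1.392e-05). The intestinal crypt genes Ephb2 and Ascl2 fell, at log2 -2.75 ± 0.34 and -2.39 ± 0.32 (adjusted p = 1.347e-04 and 1.997e-04). Among 35 Wnt ligands and receptors 13 rose and 11 fell (camera adjusted p = 0.522). Wnt6 rose by 4.77 ± 0.39 (adjusted p = 1.102e-05), Wnt7a fell from 74.3 ± 18.6 to 0.0523 ± 0.0625 CPM (-10.46 ± 0.52, adjusted p = 8.388e-07) and Wnt5b fell, at log2 -2.84 ± 0.47 (adjusted p = 7.860e-04). Ephb2 and Wnt5b were not called with the seminal vesicle covariate (-1.44 and -1.95, adjusted p = 0.132 and 0.230).

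The basal keratin genes Krt5 and Krt15 were highest in the CP1 tumours with the most uroplakin transcripts. Krt5 had 20.0, 353 and 243 CPM and Krt15 had 32.3, 538 and 316 CPM in CP1 replicates 1, 2 and 3, against 16.4 ± 10.7 and 17.3 ± 8.75 CPM in P1. The rises of 3.65 ± 0.90 and 4.10 ± 0.88 (adjusted p = 0.0081 and 0.0037) were lost with CP1 replicates 2 and 3 removed (log2 0.29 and 0.90, adjusted p = 0.800 and 0.339). With P1 replicates 1 and 2 removed they were 4.35 and 3.44 and not called (adjusted p = 0.0739 and 0.109). Krt14 fell, at log2 -4.03 ± 0.41 (adjusted p = 4.151e-05). In the basal list 5 of 15 rose and 6 fell (camera adjusted p = 0.320), against 1 and 7 without CP1 replicates 2 and 3, and 2 and 6 without P1 replicates 1 and 2. Of 22 androgen response genes 4 rose and 7 fell, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.382), with a fall of the metalloreductase gene Steap4, at log2 -3.89 ± 0.42 (adjusted p = 5.959e-05). Fkbp5 rose by 1.41 ± 0.35 (adjusted p = 0.0086). This rise was 0.92 and not called with CP1 replicates 2 and 3 removed (adjusted p = 0.180). Of 20 matrix remodelling genes 7 rose and 2 fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.416). Mmp10 and Mmp3, matrix metalloproteinase genes, rose by 3.35 ± 0.52 and 3.19 ± 0.43 (adjusted p = 5.547e-04 and 2.348e-04), and Spp1, which encodes osteopontin, fell, at log2 -2.99 ± 0.34 (adjusted p = 7.223e-05). Among 15 fibroblast genes 6 rose and 1 fell (camera adjusted p = 0.0738), and Col6a1 rose from 247 ± 40.8 to 3437 ± 371 CPM (3.80 ± 0.16, adjusted p = 4.099e-07). The seminal vesicle covariate ended the calls of Krt5, Krt15 and Fkbp5 (3.30, 1.73 and 1.81, adjusted p = 0.347, 0.617 and 0.180). It also ended those of Mmp10 and Mmp3 (3.30 and 3.28, adjusted p = 0.0849 and 0.0512).

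The remaining lists were not called in CP1 versus P1. Of the seminal vesicle list 10 of 12 measured fell (camera adjusted p = 0.0625). Higher and lower calls numbered 3 and 7 of 15 for the squamous list, 4 and 5 of 14 for neuroendocrine genes, 7 and 3 of 24 for Myc targets (5 and 1 adjusted over the list alone), 2 and 4 of 18 for FoxO targets, 7 and 10 of 24 for lineage transcription factors (8 and 11 adjusted over the list alone) and 7 and 2 of 20 for hypoxia and glycolysis. They numbered 2 and 0 of 12 for smooth muscle, 1 and 2 of 8 for skeletal muscle, 0 and 0 of 15 for endothelium, 1 and 1 of 15 for macrophages, 3 and 1 of 11 for neutrophils, 1 and 1 of 8 for adipocytes, 1 and 2 of 11 for nerve and 0 and 5 of 14 for the immediate early response. Removal of P1 replicates 1 and 2 turned the balance for Myc targets (3 and 7), FoxO targets (3 and 1), neutrophils (0 and 1) and nerve (2 and 1), and left 1 and 6 for the squamous list. Removal of CP1 replicates 2 and 3 turned it for neuroendocrine genes (3 and 2) and FoxO targets (2 and 1). It left 3 and 1 for Myc targets, 1 and 0 for neutrophils, 0 and 0 for smooth muscle and 1 gene of the seminal vesicle list lower. Either removal left 3 hypoxia and glycolysis genes higher. Where no second count is given, here and in the other comparisons, the counts were the same adjusted over the list alone.

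The comparison of CP2 with P1 asks the same of the other beta-catenin-stabilised line. In CP2 4984 genes were higher and 5013 lower, and 3511 changed by more than 2-fold in the test against a 2-fold change. Of 25 beta-catenin targets 13 rose and 8 fell, of 18 epithelial-mesenchymal transition genes 15 rose and 1 fell, and of 25 cell cycle genes 21 rose and 0 fell. Of 20 luminal genes 19 fell and 0 rose, and of 15 basal genes 10 fell and 2 rose. Camera called these 5 lists at the preset correlation and 0 lists with an estimated correlation (adjusted p = 0.279 to 0.882 for the 5). Krt42, a keratin gene, rose from 0.164 ± 0.0649 to 127 ± 23.7 CPM (log2 9.56 ± 0.31, adjusted p = 1.338e-07), Dapl1 from 0.0946 ± 0.0792 to 56.8 ± 7.55 CPM (9.12 ± 0.74, adjusted p = 6.772e-06) and Wnt16 from 0.0725 ± 0.0785 to 30.2 ± 2.78 CPM (8.55 ± 0.44, adjusted p = 5.872e-07). Slitrk1 had 0 counts in P1 and 42.3 ± 9.50 CPM in CP2, at least 1297-fold higher. Bmp5, a growth factor gene, had 2 counts over P1 and 2935 over CP2 (ratio 1621, 95% interval 448 to 13390), and Pax3, a neural crest transcription factor gene, had 1 and 1069 (ratio 1181, 211 to 46676).

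The largest falls in CP2 were of genes that P1 expressed and CP2 barely did. The kinesin gene Kif12 had 85.1 ± 11.5 CPM in P1 and 0 counts in CP2, at least 2353-fold lower, Tinag had 15.4 ± 2.12 CPM, at least 425-fold lower, and Phgr1 had 16.9 ± 8.16 CPM, at least 470-fold lower. Otop3 and Ush1c each had 1 count over CP2, against 6056 and 1754 over P1 (ratio 5483, 95% interval 984 to 216614, and ratio 1588, 285 to 62763). Gpx2, a glutathione peroxidase gene of digestive epithelium, fell from 374 ± 200 to 0.0973 ± 0.166 CPM (log2 -11.85 ± 1.13, adjusted p = 1.691e-05).

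In the list of beta-catenin targets 13 of 25 genes rose and 8 fell in CP2, also adjusted over the list alone (camera adjusted p = 0.0059; adjusted p = 0.326 with an estimated correlation). Axin2 rose to 610 ± 38.7 CPM (log2 4.41 ± 0.22, adjusted p = 5.249e-07), Apcdd1 to 3510 ± 370 CPM (7.75 ± 0.52, adjusted p = 2.168e-06) and Notum, a secreted Wnt deacylase, from 4.99 ± 0.992 to 543 ± 96.4 CPM (6.76 ± 0.39, adjusted p = 9.367e-07). Ephb2 and Ascl2 fell, as they did in CP1, by -3.77 ± 0.33 and -4.33 ± 0.35 (adjusted p = 9.315e-06 and 6.448e-06). Of 35 Wnt ligands and receptors 17 rose and 12 fell (camera adjusted p = 0.198). Wnt6 rose to 160 ± 18.9 CPM (7.20 ± 0.42, adjusted p = 9.842e-07) and Wnt7a fell to 2.01 ± 0.614 CPM (-5.20 ± 0.32, adjusted p = 1.268e-06).

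In the luminal list 19 of 20 genes fell and 0 rose in CP2, also adjusted over the list alone (camera adjusted p = 3.234e-13; adjusted p = 0.279 with an estimated correlation). Psca fell from 50.2 ± 28.9 to 0.0961 ± 0.0373 CPM (log2 -8.96 ± 1.21, adjusted p = 1.563e-04) and Prom1 to 4.88 ± 3.79 CPM (-8.47 ± 0.67, adjusted p = 5.740e-06). Krt8, a luminal keratin gene, fell from 4557 ± 1827 to 51.5 ± 44.7 CPM (-6.47 ± 0.76, adjusted p = 6.563e-05) and Cdh1, the E-cadherin gene, from 1414 ± 125 to 25.1 ± 7.93 CPM (-5.82 ± 0.45, adjusted p = 5.145e-06). In the basal list 10 of 15 fell and 2 rose, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.0197; adjusted p = 0.882 with an estimated correlation), with Sfn (-3.86 ± 0.50, adjusted p = 1.246e-04). The call of the basal list was lost without P1 replicate 1 (0.0642) and with P1 replicates 1 and 2 removed (0.0687). Among 24 lineage transcription factors 4 rose and 13 fell (camera adjusted p = 0.195). The epithelial factor genes Elf3 and Ehf fell, at log2 -6.61 ± 0.50 and -4.72 ± 0.24 (adjusted p = 4.238e-06 and 5.937e-07), and Hoxa13, of the caudal urogenital tract, rose by 3.14 ± 0.26 (adjusted p = 7.765e-06).

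Of 18 epithelial-mesenchymal transition genes 15 rose and 1 fell in CP2, also adjusted over the list alone (camera adjusted p = 1.861e-08; adjusted p = 0.279 with an estimated correlation). S100a4 rose to 277 ± 67.5 CPM (log2 4.39 ± 0.38, adjusted p = 8.912e-06) and Twist1 from 7.60 ± 1.27 to 149 ± 6.28 CPM (4.29 ± 0.16, adjusted p = 1.428e-07), while the fibronectin gene Fn1 fell, at log2 -1.05 ± 0.25 (adjusted p = 0.0046; -0.07 and adjusted p = 0.918 with the seminal vesicle covariate). Transcripts of the fibroblast list took 1.24% to 1.48% of the counts in CP2 tumours, against 0.573% to 1.09% in P1. In the cell cycle list 21 of 25 rose and 0 fell, or 21 and 1 adjusted over the list alone (camera adjusted p = 7.314e-05; adjusted p = 0.882 with an estimated correlation), among them E2f1 (1.72 ± 0.16, adjusted p = 1.480e-05) and the spindle checkpoint gene Bub1 (1.69 ± 0.16, adjusted p = 1.474e-05). With P1 replicates 1 and 2 removed, 12 of 25 cell cycle genes rose and 1 fell, and the list was not called (0.0560).

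Genes of the immune lists were called in both directions in CP2. In the interferon list 8 of 24 rose and 2 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.460). Ifit2 and Ifit3 rose by 2.34 ± 0.40 and 2.13 ± 0.46 (adjusted p = 6.942e-04 and 0.0029), and Oasl1 fell, at log2 -1.81 ± 0.30 (adjusted p = 6.412e-04). Gbp2 had 71.1, 341 and 38.6 CPM in P1 replicates 1, 2 and 3 and 34.2 to 57.2 in the CP2 tumours. Its fall of -1.58 ± 0.60 (adjusted p = 0.0458) rested on P1 replicate 2, without which it was -0.15 (adjusted p = 0.708, in a range of 0.0080 to 0.708 over its alternatives). In the antigen presentation list 2 of 15 rose and 7 fell (camera adjusted p = 0.460). The class I genes H2-D1 and H2-K1 rose by 0.71 ± 0.17 and 0.62 ± 0.18 (adjusted p = 0.0055 and 0.0151), and the H2-K1 call was lost without P1 replicate 1 (0.0573). With P1 replicates 1 and 2 removed the values were 0.58 and 0.67 and both calls were lost (adjusted p = 0.0770 and 0.0679). The seminal vesicle covariate gave 0.33 and 0.14 (adjusted p = 0.500 and 0.792). The class II genes Cd74 and H2-Ab1 fell, at log2 -3.03 ± 0.45 and -2.51 ± 0.39 (adjusted p = 3.113e-04 and 4.178e-04). In the lymphocyte list 4 of 17 rose and 6 fell (camera adjusted p = 0.665), with rises of Prf1, the perforin gene, from 9.61 ± 1.99 to 176 ± 31.2 CPM (4.19 ± 0.32, adjusted p = 4.860e-06) and of Gzmb from 19.1 ± 3.35 to 90.2 ± 18.6 CPM (2.24 ± 0.32, adjusted p = 2.389e-04). Removal of P1 replicates 1 and 2 gave 5 rises and 2 falls among lymphocyte genes, and 2 and 4 among antigen presentation genes. The covariate ended the calls of Ifit2, Ifit3 and Oasl1 (1.82, 1.03 and -1.95, adjusted p = 0.0939, 0.344 and 0.0552), of Gbp2 and H2-Ab1 (-2.62 and -2.59, adjusted p = 0.118 and 0.0512) and of Gzmb (1.61, adjusted p = 0.0721).

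Of 22 androgen response genes 4 rose and 10 fell in CP2 (camera adjusted p = 0.198). Rab3b rose by 4.26 ± 0.53 on the log2 scale (adjusted p = 8.920e-05). Pbsn, the androgen-driven probasin gene, had 388, 119 and 1394 CPM in P1 replicates 1 to 3 and 3.92 ± 5.55 in CP2 (-7.34 ± 2.21, adjusted p = 0.0174), a call lost with no filter on low counts (0.0664) and with the seminal vesicle covariate (-12.10, 0.185). Spink1 had 729, 0.873 and 91.6 CPM in P1 and 1.71 ± 2.33 in CP2 (-7.32 ± 1.76, adjusted p = 0.0056), and its direction turned with the seminal vesicle covariate (4.60, adjusted p = 0.157). In the matrix remodelling list 8 of 20 rose and 6 fell (camera adjusted p = 0.783). Mmp9 rose from 17.8 ± 6.23 to 940 ± 295 CPM (5.72 ± 0.42, adjusted p = 3.751e-06) and Mmp10 by 5.50 ± 0.55 (adjusted p = 2.364e-05), while Spp1 and Ccn2 fell, at log2 -3.66 ± 0.31 and -3.70 ± 0.57 (adjusted p = 8.381e-06 and 3.663e-04). Smooth muscle genes fell in 7 of 12 and rose in 2 (camera adjusted p = 0.487), with Cnn1 (-3.24 ± 0.81, adjusted p = 0.0068) and Lmod1 (-3.14 ± 0.69, adjusted p = 0.0032). The mean log2 CPM of the list was 7.69, 6.64 and 5.87 in P1 replicates 1, 2 and 3 and 5.00 to 5.95 in CP2. Both calls were lost with P1 replicates 1 and 2 removed (log2 -2.02 and -1.90, adjusted p = 0.155 and 0.0765), and 3 smooth muscle genes then rose and 1 fell. The covariate gave -1.49 for Cnn1, -1.75 for Lmod1 and -2.39 for Ccn2, none of them called (adjusted p = 0.534, 0.444 and 0.119).

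The seminal vesicle list fell in 11 of 12 genes in CP2 (camera adjusted p = 0.129). In the other lists that were not called, higher and lower calls numbered 3 and 7 of 15 for the squamous list (3 and 8 adjusted over the list alone), 4 and 6 of 14 for neuroendocrine genes (4 and 7), 2 and 9 of 24 for Myc targets, 4 and 8 of 20 for NF-kappaB targets, 5 and 8 of 18 for FoxO targets and 1 and 3 of 20 for hypoxia and glycolysis. They numbered 8 and 6 of 15 for fibroblasts (8 and 7 adjusted over the list alone), 2 and 2 of 8 for skeletal muscle, 0 and 9 of 15 for endothelium (0 and 10), 0 and 1 of 15 for macrophages, 0 and 3 of 11 for neutrophils (0 and 1), 0 and 2 of 8 for adipocytes (0 and 1), 2 and 3 of 11 for nerve and 1 and 9 of 14 for the immediate early response (2 and 9). Removal of P1 replicates 1 and 2 gave 8 and 1 for fibroblasts, 0 and 5 for endothelium, 4 and 5 for NF-kappaB targets, 2 and 6 for neuroendocrine genes and 5 and 5 for FoxO targets, and 7 seminal vesicle list genes fell. Removal of CP1 replicates 2 and 3, which share the estimate of the spread, gave 2 and 1 for nerve and 0 and 5 for neutrophils.

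**Figure D3:**
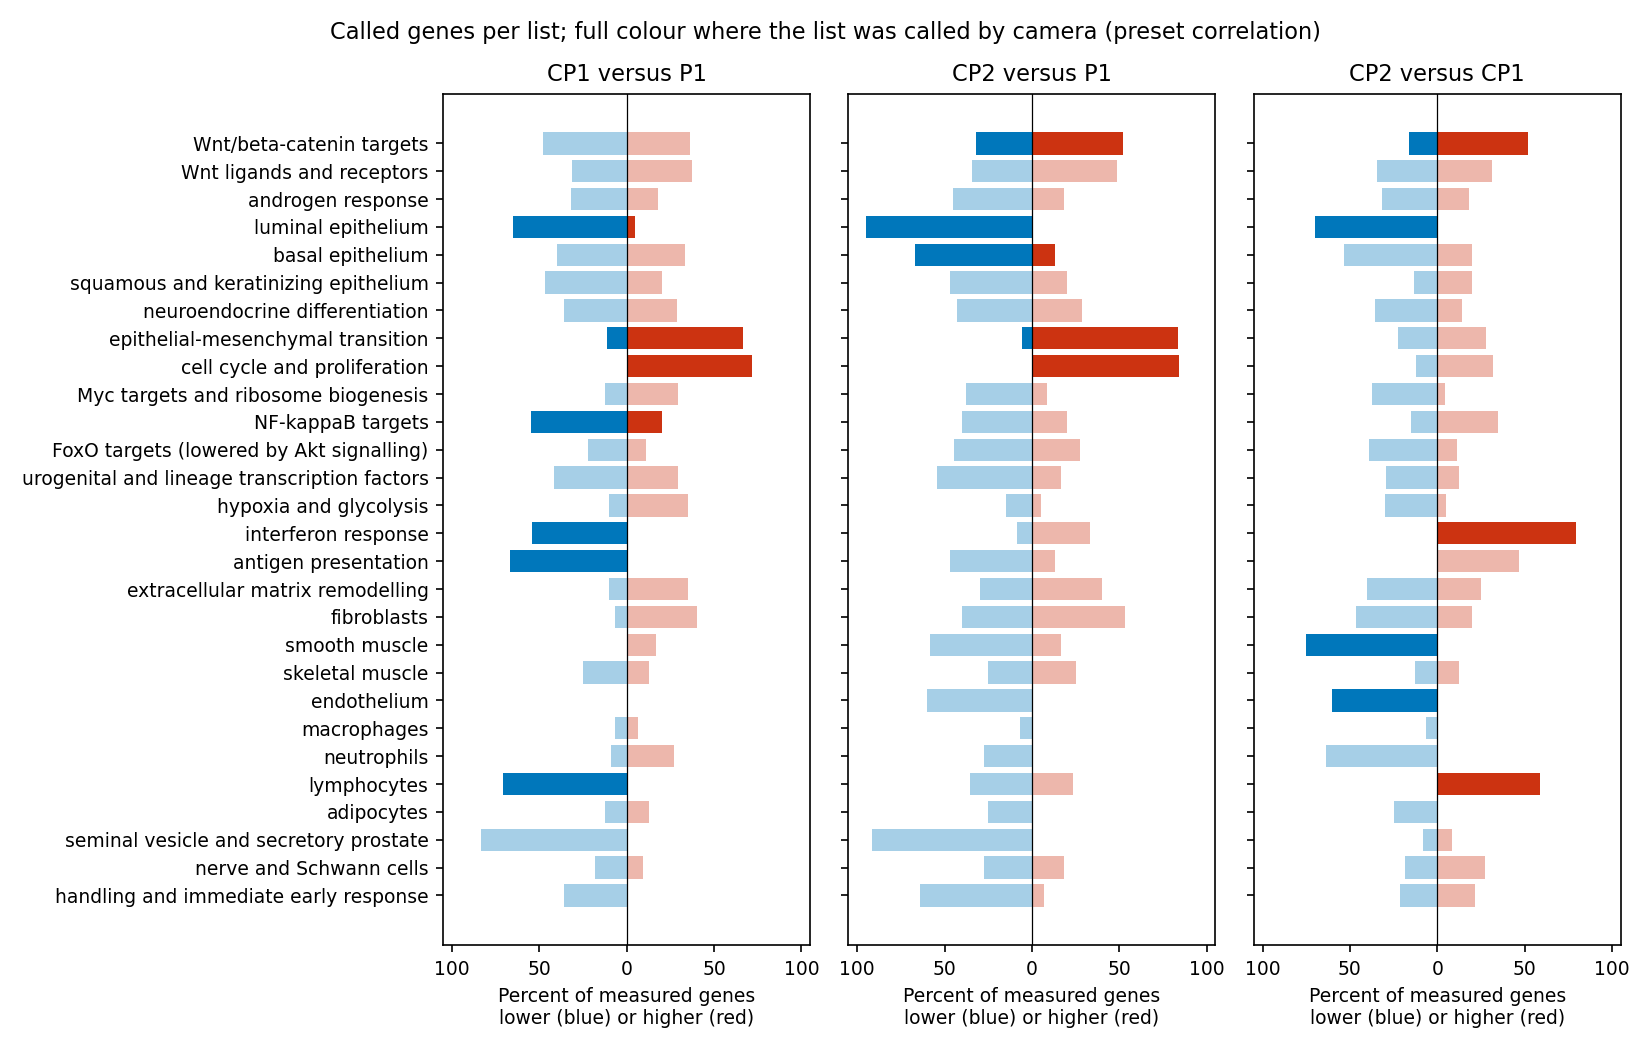
For each of the 28 lists (vertical axis) the bars give the percent of its measured genes called lower (blue, to the left) and higher (red, to the right) in 3 comparisons, in full colour where camera called the list at the preset correlation and pale elsewhere. The luminal list lies to the left in every panel, with 13 of 20, 19 of 20 and 14 of 20 genes lower.

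The 2 contrasts against P1 were set side by side to ask which changes both lines share. In both lines 2561 genes were higher and 2752 lower, 5313 in all, where independent lists of the same sizes would share 1117 and 1123. Simulated unchanged groups, both set against the same simulated P1 group, shared 0. Across genes, which are not independent replicates, log2 fold changes correlated at 0.690, against 0.524 in the simulation, and their covariance was 2.16 against 0.0692. Signs matched for 72.4% of genes against 67.7%. With 3 P1 libraries the controls could not be split into 2 parts of at least 2, and part of the excess may come from the shared controls. The simulated groups had 1 common mean per gene, so almost no calls were possible there. The P1 libraries of the simulation were drawn too, with the same spread per gene in every line. The real P1 libraries and their differences from tumour to tumour are therefore not part of this reference. A trait of the P1 line alone counts as a change in both lines. Neither reference separates such a trait from a change that CP1 and CP2 share. Of the 5313 genes, 2017 also differed between CP2 and CP1, 1242 of them with the larger change in CP2. Opposite calls were made for 495 genes, and CP2 versus CP1 was called for all 495.

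The mean of both CP lines differed from P1 in 9234 genes, 4606 higher and 4628 lower, and in 6153 when CP1 and CP2 were pooled as 1 group of 7. Wnt5a was higher by 5.19 ± 0.40 on the log2 scale, and Ctnnb1 and Myc were lower, at log2 -0.86 ± 0.09 and -0.86 ± 0.11 (adjusted p = 4.821e-06, 4.291e-05 and 1.111e-04). The luminal list (16 of 20 lower, 0 higher, also adjusted over the list alone), the epithelial-mesenchymal transition list (14 of 18 higher, 0 lower, also adjusted over the list alone) and the cell cycle list (20 of 25 higher, 1 lower, 21 and 1 adjusted over the list alone) were called, at camera adjusted p = 4.822e-12, 1.839e-07 and 1.357e-05. With an estimated correlation the adjusted p was 0.313, 0.313 and 0.744. With P1 replicates 1 and 2 removed 10 of 25 cell cycle genes were higher and 1 lower. Nkain2, Adcy1 and Cpne4, genes of neural tissue, rose by 6.86 ± 0.23, 7.22 ± 0.37 and 7.57 ± 0.43 (adjusted p = 7.390e-08, 3.401e-07 and 6.937e-07). The neural cadherin gene Cdh2 rose by 2.83 ± 0.15 and S100a4 by 4.73 ± 0.37 (adjusted p = 5.365e-07 and 5.138e-06). Prom1 fell, at log2 -8.59 ± 0.55 (adjusted p = 1.331e-06), and Tm4sf20, Tff2, Reg1 and Kif12 fell, at log2 -10.12 ± 0.49, -10.59 ± 0.48, -10.34 ± 0.48 and -12.24 ± 0.20 (adjusted p = 2.532e-07, 1.837e-07, 2.061e-07 and 7.922e-08). Fits of Tm4sf20, Tff2, Reg1 and Kif12 rest on 0 to 15 counts over a CP group and depend on the prior count.

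The comparison of CP2 with CP1 asks how far lines of the same named genotype differ. In CP2 3753 genes were higher and 3867 lower, 7620 in all, and 4177 with CP1 replicates 2 and 3 removed. In the test against a 2-fold change 1807 changed. Higher in CP2 were 13 of 25 beta-catenin targets, 19 of 24 interferon and 10 of 17 lymphocyte genes, with 4, 0 and 0 lower. Lower in CP2 were 14 of 20 luminal, 9 of 12 smooth muscle and 9 of 15 endothelial genes, with 0 higher in each. Camera called these 6 lists at the preset correlation and 0 lists with an estimated correlation (adjusted p = 0.242 to 0.854 for the 6). With CP1 replicates 2 and 3 removed, 12 interferon genes were higher, and 8 luminal, 0 smooth muscle and 4 endothelial genes were lower. Krt42 and Wnt16, both near 0 in CP1, were higher by 10.49 ± 0.34 and 9.16 ± 0.46 on the log2 scale, and Slitrk1 by 9.36 ± 0.46 (adjusted p = 2.521e-07, 2.153e-06 and 6.773e-06). Bex1 and the granzyme gene Gzmg rose from 0.409 ± 0.288 to 89.8 ± 10.2 CPM and from 2.03 ± 1.71 to 429 ± 85.1 CPM (7.71 ± 0.47 and 7.70 ± 0.66, adjusted p = 4.517e-06 and 2.364e-05). Zic2, a neural transcription factor gene, had 1 count over CP1 and 1376 over CP2 (ratio 1385, 95% interval 248 to 54752). Alb, the albumin gene, had 0 counts in CP1 and 1.13, 0.0491, 133 and 2.98 CPM in CP2 replicates 1 to 4, and by summed counts the gene was at least 1007-fold higher in CP2. CP2 replicate 3 sets this sum, and without it the fitted difference was 8.20 with the lowest adjusted p, 0.0155. The adjusted p of 0.0359 ranged from there to 0.264, and 10 of 19 alternatives did not call Alb.

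Lower in CP2 than in CP1 were Nell2 (77.6 ± 30.5 to 0.106 ± 0.0937 CPM, log2 -9.43 ± 0.49, adjusted p = 2.226e-06) and a set of bladder lining genes. Upk1a had 19.5, 423 and 177 CPM in CP1 replicates 1, 2 and 3 and 0.719 ± 0.549 in CP2 (-8.17 ± 1.06, adjusted p = 2.617e-04), and Psca had 12.1, 231 and 71.2 CPM and 0.0961 ± 0.0373 (-10.02 ± 1.21, adjusted p = 1.668e-04). Snx31 had 4438 counts over CP1 and 3 over CP2 (ratio 1469, 95% interval 503 to 7128). Msmb, a secretory prostate gene, had 52.1 CPM in CP1 replicate 1 and 0 counts in the other CP1 and all CP2 tumours. By summed counts it was at least 488-fold lower in CP2 (adjusted p = 0.0463), and without CP1 replicate 1 both groups stood at 0 counts. The adjusted p ranged from 0.0013 to 1, and 12 of 17 alternatives did not call Msmb. Among them were no filter on low counts (0.194), the removal of P1 replicates 1 and 2 (0.115), the seminal vesicle covariate (0.0666) and each P1 or CP2 tumour left out (0.0626 to 0.0822).

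Of 25 beta-catenin targets 13 were higher and 4 lower in CP2 than in CP1, also adjusted over the list alone (camera adjusted p = 2.316e-05; adjusted p = 0.242 with an estimated correlation), and 12 and 2 without CP1 replicates 2 and 3. Sp5, a direct target, rose from 1.04 ± 0.650 to 83.6 ± 7.33 CPM (log2 6.30 ± 0.42, adjusted p = 6.713e-06), Wif1, a secreted Wnt inhibitor, from 9.15 ± 10.7 to 659 ± 47.3 CPM (6.16 ± 0.89, adjusted p = 4.649e-04) and Axin2 by 1.5 ± 0.19 (adjusted p = 2.114e-04), while Ascl2 fell, at log2 -1.94 ± 0.39 (adjusted p = 0.0030; -1.35 and adjusted p = 0.149 with CP1 replicates 2 and 3 removed). Of 35 Wnt ligands and receptors 11 rose and 12 fell, or 12 and 12 adjusted over the list alone (camera adjusted p = 0.239; 9 and 5 with CP1 replicates 2 and 3 removed), and the Wnt antagonist gene Sfrp1 fell, at log2 -1.73 ± 0.31 (adjusted p = 0.0016). In the luminal list 14 of 20 fell and 0 rose, or 16 and 0 adjusted over the list alone (camera adjusted p = 1.998e-05; adjusted p = 0.854 with an estimated correlation), with Krt7 falling from 230 ± 196 to 5.48 ± 3.33 CPM (-5.39 ± 0.81, adjusted p = 5.816e-04). Without CP1 replicates 2 and 3, which held the most urothelial transcripts, 8 of 20 luminal genes fell and Krt7 was lower at log2 -2.36 (adjusted p = 0.0167). Of 18 mesenchymal genes 5 rose and 4 fell (camera adjusted p = 0.0639; 5 and 6 with P1 replicates 1 and 2 removed). Twist1 and Snai2 rose by 5.60 ± 0.17 and 2.76 ± 0.34 (adjusted p = 2.521e-07 and 1.941e-04), and Fn1 fell, at log2 -1.53 ± 0.25 (adjusted p = 8.940e-04).

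In the interferon list 19 of 24 genes were higher in CP2 than in CP1 and 0 lower, or 20 and 0 adjusted over the list alone (camera adjusted p = 1.569e-06; adjusted p = 0.854 with an estimated correlation). Cxcl9 and Cxcl10 rose by 5.23 ± 1.12 and 3.77 ± 0.68 on the log2 scale (adjusted p = 0.0043 and 0.0016). In the antigen presentation list 7 of 15 rose and 0 fell (camera adjusted p = 0.0639), with Nlrc5, a regulator of class I genes, and the peptide transporter gene Tap1 (2.29 ± 0.61 and 2.16 ± 0.34, adjusted p = 0.0125 and 7.634e-04). In the lymphocyte list 10 of 17 rose and 0 fell, or 11 and 0 adjusted over the list alone (camera adjusted p = 2.150e-06; adjusted p = 0.385 with an estimated correlation), with Prf1 and Gzmb (7.24 ± 0.39 and 6.81 ± 0.43, adjusted p = 2.496e-06 and 5.430e-06). Among 20 NF-kappaB genes 7 rose and 3 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.0639). Traf1 and Nfkb2 rose by 2.93 ± 0.26 and 2.09 ± 0.24 (adjusted p = 2.728e-05 and 1.217e-04). Without CP1 replicates 2 and 3, 3 of 15 antigen presentation genes rose and 4 fell. Cxcl9 (log2 5.03, adjusted p = 0.137), Cxcl10 (3.93, 0.0579) and Nlrc5 (2.79, 0.0727) were then not called.

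Smooth muscle genes were lower in CP2 than in CP1 in 9 of 12, or 10 adjusted over the list alone (camera adjusted p = 0.0388; adjusted p = 0.854 with an estimated correlation), and endothelial genes in 9 of 15, or 10 adjusted over the list alone (camera adjusted p = 0.0388; adjusted p = 0.854 with an estimated correlation). Actg2 had 45.5, 584 and 994 CPM and Des had 55.6, 614 and 1112 CPM in CP1 replicates 1, 2 and 3, and they fell, at log2 -5.22 ± 0.99 and -3.67 ± 0.87 in CP2 (adjusted p = 0.0022 and 0.0074). The mean log2 CPM of the smooth muscle list was 5.76, 7.93 and 8.42 in CP1 replicates 1, 2 and 3. With CP1 replicates 2 and 3 removed, the smooth muscle list (0.842), Actg2 (log2 -1.65, 0.217) and Des (log2 -0.25, 0.859) were not called. Fry, which does not compare a list with other genes, called neither list (adjusted p = 0.0913 for smooth muscle and 0.0580 for endothelium). The smooth muscle call was also lost without CP1 replicate 2 (0.0684), CP1 replicate 3 (0.109), CP2 replicate 1 (0.0509), CP2 replicate 2 (0.0557) or P1 replicate 3 (0.0597). The endothelial call was lost without CP1 replicate 1 (0.117), CP2 replicate 2 (0.0557), CP2 replicate 3 (0.0662) or P1 replicate 3 (0.0597). Emcn and Esam, of endothelium, fell, at log2 -1.26 ± 0.18 and -1.08 ± 0.28 (adjusted p = 4.849e-04 and 0.0118).

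In the basal list 3 of 15 genes were higher and 8 lower in CP2 than in CP1 (camera adjusted p = 0.159). Krt15 and Col17a1 fell, at log2 -6.13 ± 0.87 and -4.49 ± 0.79, and Krt14 rose by 2.77 ± 0.38 (adjusted p = 4.284e-04, 0.0014 and 3.651e-04). With CP1 replicates 2 and 3 removed, Krt15 was lower at log2 -2.93 (adjusted p = 0.0093), and the Col17a1 call was lost (-1.91, adjusted p = 0.105). Of the basal list 4 of 15 genes were then higher and 4 lower. Of 22 androgen response genes 4 rose and 7 fell, or 4 and 8 adjusted over the list alone (camera adjusted p = 0.608; 1 and 7 with CP1 replicates 2 and 3 removed). Higher and lower calls in the other lists numbered 3 and 2 of 15 for the squamous list, 2 and 5 of 14 for neuroendocrine genes, 8 and 3 of 25 for the cell cycle, 1 and 9 of 24 for Myc targets, 2 and 7 of 18 for FoxO targets, 3 and 7 of 24 for lineage transcription factors and 1 and 6 of 20 for hypoxia and glycolysis. They numbered 5 and 8 of 20 for matrix remodelling (5 and 9 adjusted over the list alone), 3 and 7 of 15 for fibroblasts, 1 and 1 of 8 for skeletal muscle, 0 and 1 of 15 for macrophages (0 and 0), 0 and 7 of 11 for neutrophils, 0 and 2 of 8 for adipocytes, 1 and 1 of 12 for the seminal vesicle list (0 and 0), 3 and 2 of 11 for nerve and 3 and 3 of 14 for the immediate early response (3 and 4). Without CP1 replicates 2 and 3 they were 0 and 0 for the cell cycle, 0 and 4 for Myc and FoxO targets each, 3 and 4 for lineage transcription factors and 1 and 3 for hypoxia and glycolysis. They were then 4 and 4 for matrix remodelling, 0 and 1 for neutrophils and 1 and 3 for the immediate early response. Removal of P1 replicates 1 and 2 gave 5 and 7 for lineage transcription factors.

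**Figure D4:**
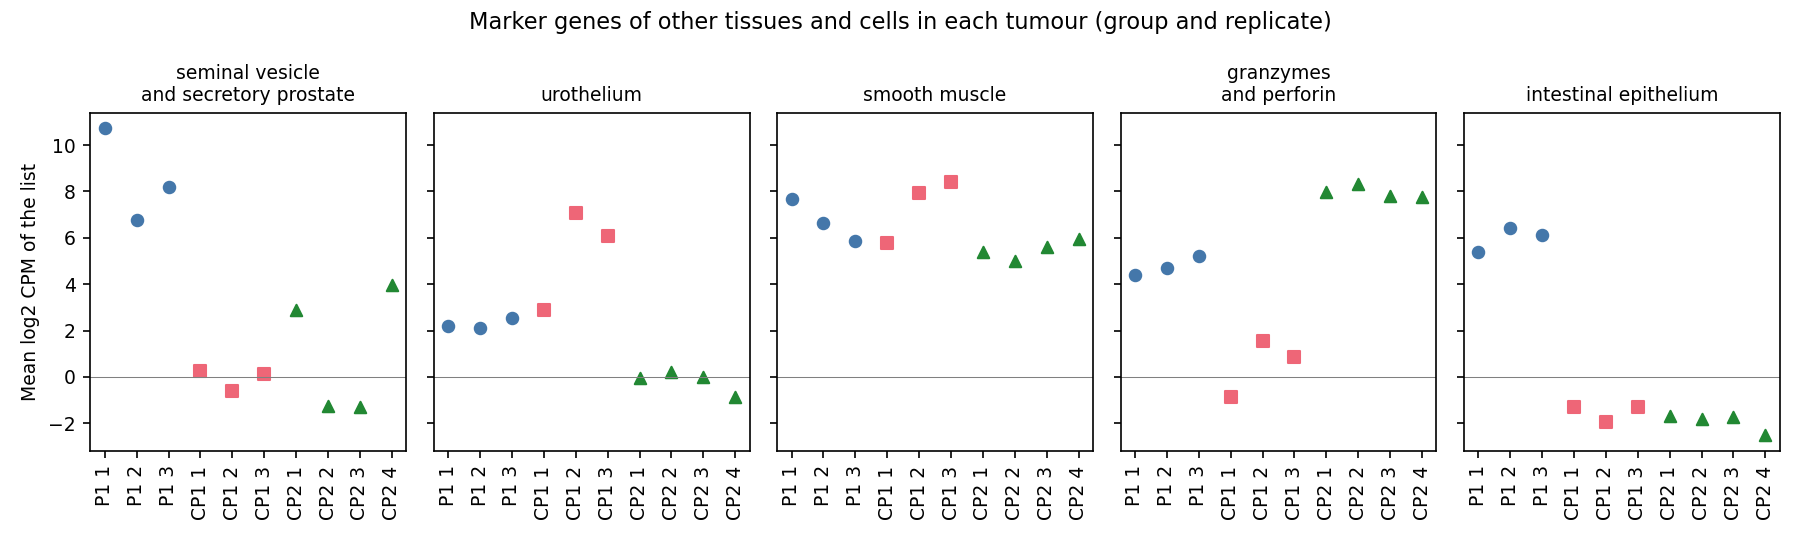
Each point is the mean log2 CPM (vertical axis) of a marker list in a tumour (horizontal axis, line and replicate), for 5 lists. The seminal vesicle and secretory prostate list lay between 6.76 and 10.72 in P1, urothelial genes at 7.06 and 6.08 in CP1 replicates 2 and 3, and granzymes and perforin between 7.78 and 8.32 in CP2.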

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

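3 patterns were weighed, and all tests of an explanation for them were chosen after the result was seen, while the counts over other splits of the tumours were set beforehand. The SDs between tumours of the mean log2 CPM, 2.01 for the seminal vesicle genes in P1, 2.19 for the urothelial genes in CP1 and 0.251 for the granzyme genes in CP2, were also set against those of other lists. The 95th percentiles of 10000 random lists matched on expression were 0.321, 0.201 and 0.108, and the largest SDs of the other fixed lists were 1.56, 1.42 and 2.74. These SDs restate patterns seen in the same tumours, and 2 of the lists were written after their genes were seen, so they decide nothing here.

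Seminal vesicle genes were high in P1 and differed between its tumours. They took 17.2%, 6.98% and 1.86% of the counts in replicates 1, 2 and 3. The whole list holds genes of more than 1 gland (SDs of the log2 ratios between P1 tumours 1.61 to 5.70), so its 7 Svs genes were taken alone to test a single gland. Between P1 replicates 1 and 3 their SD was 0.403, so host gland of 1 profile in different amounts may account for both, but that profile is argued against for replicate 2 (SD 4.46 and 4.43 to replicates 1 and 3; ratio of Svs1 to Svs2 3.134e-04 against 0.367 and 0.247). Other host glands, and expression by all or part of the tumour cells, stay open and were not tested.

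Urothelial genes were high in CP1 replicates 2 and 3. Host urothelium taken up in different amounts may account for them, since the ratio of replicate 2 to 3 was alike over the 13 genes (median log2 0.99, SD 0.438). CP1 replicate 1, which did not enter this ratio, held such transcripts at lower levels. It had 8.16 CPM of Upk3a against 0.116 ± 0.122 in P1, and 19.5 CPM of Upk1a against 0.719 ± 0.549 in CP2. Bladder wall with urothelium and muscle in 1 proportion is argued against: smooth muscle genes went the other way (median log2 -0.57, SD 0.298), a difference of 1.56. The list was written after its genes were seen, 4 of the 13 stand in the fixed basal or luminal lists, and expression by all or part of the tumour cells stays open and was not tested.

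Granzyme and perforin genes were high in all 4 CP2 tumours. Infiltrating lymphocytes are argued against as the whole source: the 15 other measured members of the lymphocyte list had a median log2 fold change of -0.11 (SD 1.93) against 3.32 (SD 0.668) for these genes, a difference of -3.43. They include Gzma, a granzyme gene that fell (-2.27 ± 0.56, adjusted p = 0.0060) and is not among the 7 genes, the median without it was 0.06 (SD 1.95), and the most abundant in CP2 were Il2rb at 45.8, Klrk1 at 4.47, Nkg7 at 4.05 and Cd4 at 3.84 CPM. Reads shared within the granzyme family do not account for Prf1, which is no granzyme and rose by 4.19. For the granzyme genes themselves such sharing was not tested, and the rise of Prf1 does not bear on it. Expression by the CP2 tumour cells stays open and was not tested.

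The counts of changed genes were set against other splits of the tumours. For CP1 versus P1 the 10 splits are too few for a share under 0.05: the real split gave 6123 genes and the highest other 0 (1 split as large, the real one). For CP2 versus P1 1 of 35 splits, the real one, gave 9594 genes and the highest other 0, and for CP2 versus CP1 1 of 35 gave 8388 and the highest other 0. For both CP lines pooled against P1, 1 of 100 splits drawn from 120 gave 6153 and the highest other 1. Every other split mixes lines within a group, which widens the spread there, so few calls follow from any difference between lines. The counts thus follow the line labels. As all tumours of P1, CP1 or CP2 come from 1 line each, the splits cannot exclude chance differences between lines.

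In 144 gap tests over the 4 CP2 tumours, a tumour stood apart from the rest in 11. The bound used gives about 1 in 20 by chance for normal values. Genes were tested as untransformed CPM, so their chance rate is not known. The gap took this share of the range: Alb 0.978, Col17a1 0.977, Des 0.863, Fkbp5 0.847, Gbp2 0.837, Gpx2 0.867, Rrm2 0.852, Tap1 0.851, and 1 for Otop3, Snx31 and Ush1c. Otop3, Snx31 and Ush1c had counts in only 1 of the 4 tumours, which fixes their gap at 1.

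CP1 and CP2 differed in their change against P1, by the test of CP2 versus CP1, in 495 genes called in opposite directions and in 82 of the 116 named genes. The named genes with opposite calls differed by 7.71 (Bex1), -4.49 (Col17a1), -1.75 (Foxa1), 6.81 (Gzmb), 7.70 (Gzmg), 1.73 (H2-D1), 2.02 (H2-K1), -6.13 (Krt15), -9.43 (Nell2), 7.24 (Prf1), 6.30 (Sp5), 2.93 (Traf1), 5.60 (Twist1), 6.16 (Wif1) and 9.96 (Zic2) on the log2 scale, CP2 minus CP1. Camera called CP2 versus CP1 for 3 lists to which it gave opposite signs against P1, the interferon response (adjusted p = 1.569e-06), lymphocytes (adjusted p = 2.150e-06) and smooth muscle (adjusted p = 0.0388). With an estimated correlation the adjusted p was 0.854, 0.385 and 0.854. In CP2 versus P1 all 3 were not called (adjusted p = 0.460, 0.665 and 0.487). The lymphocyte list had no clear direction there, with 4 genes higher, 6 lower, a median of 0.22 and a mean of -0.19 on the log2 scale.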

How the results depend on the processing

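The alternatives that remove P1 replicates 1 and 2 or CP1 replicates 2 and 3, add the seminal vesicle covariate, remove the seminal vesicle genes or thin the counts were chosen after the data were seen. RLE factors, no filter, DESeq2, removal of the seminal vesicle genes and thinning left every count of genes within 1.5 times its value, and RLE, the removal and thinning did so for called lists. Lists were not run with no filter or DESeq2. The test against a 2-fold change gave 2661 genes for CP1 versus P1, 3511 for CP2 versus P1, 1807 for CP2 versus CP1, 2830 for the mean and 1702 alike in both, by its stricter construction. With only the tumours of the lines compared, 6123 genes were called for CP1 versus P1, against 7906 in the main fit. There were 9594 for CP2 versus P1 (9997 in the main fit) and 8388 for CP2 versus CP1 (7620). Pooling CP1 and CP2 gave 6153 for the mean. The seminal vesicle covariate, which follows the line closely, gave 2447, 4087, 2791 for the mean and 1728 alike, with 11, 8 and 11 lists called against P1. It averages genes that include Svs2, Svs4 and Pate4, so the loss of their calls follows from its construction. Without CP1 replicates 2 and 3, CP2 versus CP1 gave 4177 genes from fewer samples, and the mean 5 lists. Without P1 replicates 1 and 2, lists called were 3 for CP2 versus P1, 10 for CP2 versus CP1 and 5 for the mean, and the cause was not tested. With an estimated correlation 0 lists were called in each contrast, and fry, which does not compare a list with other genes, called 13, 14 and 14 against P1.

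Leaving out each tumour in turn gave 6892 to 8033 genes for CP1 versus P1, 8960 to 10208 for CP2 versus P1, 6284 to 8705 for CP2 versus CP1, 7929 to 9186 for the mean and 4578 to 5348 alike. Lists called ranged from 7 to 9, 4 to 6, 4 to 11 and 3 to 6. They moved by over 1.5 times without CP1 replicate 1 (11 for CP2 versus CP1), and for the mean without P1 replicate 2 (5) and CP1 replicate 3 (6).

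Title numbers 19 and 21 occur in P1 and CP2. Same-numbered tumours had residual correlations of -0.173 and -0.0625, and the other pairs -0.189 to 0.238. These values show no sign that the numbers pair the tumours, but so few pairs cannot exclude it. With the number as a replicate block, 9537 genes were called for CP2 versus P1, 8160 for the mean and 4467 alike. In CP2 versus P1 Gbp2 (-1.26, adjusted p = 0.129), Pbsn (-7.11, 0.0655) and Spink1 (-4.78, 0.0745) were not called.

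Of 156 results for named genes, 103 kept their direction and side of the threshold in every alternative that gave a value. Over all of them 119 calls were lost with the direction kept, 3 more as it turned, and none gained. A gain was possible only for Ctnnb1 in CP2 versus CP1, since every other result was already called in the main test. The absence of gains therefore follows from the selection and is no sign of stability. Of the 119, 32 were lost with the covariate, 22 in the 2-fold test and 19 without CP1 replicates 2 and 3. 3 directions turned: Msmb, CP2 versus CP1, without CP1 replicate 1 (0, with both groups at 0 counts; -12.41 to 0 over the tumours left out), Gbp2 in CP2 versus P1 without P1 replicates 1 and 2 (0.35, adjusted p = 0.471, in a range of 0.0080 to 0.708) and Spink1 in CP2 versus P1 with the covariate (4.60, adjusted p = 0.157). The cause was not tested for the last 2. Of the lists called in the main test, none turned in its tested direction under the alternatives run for it. Lists that were not called were not checked in this way. For some of them the balance of higher and lower calls turned when replicates were removed, as given in the results. CP2 libraries are the shallowest, and thinning all to the smallest total ended no call of a named gene.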

Other observations

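Genes of digestive epithelium were far higher in P1 than in both CP lines, where most of them were detected at low levels. The list for intestinal epithelium was written after these genes were seen among the largest falls, so its count is no independent evidence. All 16 of its genes were lower in CP1 and in CP2 than in P1, at a median log2 fold change of -8.18 and -9.22 (-8.18 and -9.01 with the gene at 0 counts set to its bound), and 2 of 16 were lower in CP2 than in CP1. Hnf4a, a transcription factor gene of liver and gut, had 254 ± 11.1 CPM in P1, 2.38 ± 3.33 in CP1 and 0.789 ± 0.594 in CP2 (mean of both CP lines against P1, log2 -7.53 ± 0.71, adjusted p = 1.636e-05). Cdx2, which specifies intestine, had 18.7 ± 4.99, 0.0857 ± 0.0311 and 0.134 ± 0.0895 CPM (-7.40 ± 0.32, adjusted p = 1.489e-07), and the brush border gene Vil1 had 253 ± 39.2, 0.277 ± 0.196 and 0.873 ± 0.633 CPM (-9.03 ± 0.39, adjusted p = 1.552e-07). No explanation was tested.

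2 genes outside the rule stood out in P1. Mycn had 41.7 ± 3.67 CPM in P1, 0.175 ± 0.102 in CP1 and 1.99 ± 0.256 in CP2 (-6.11 ± 0.19, adjusted p = 6.988e-08), and Cdkn2a, the p16 and Arf tumour suppressor locus, had 24.3 ± 8.14, 0.679 ± 0.0294 and 0.497 ± 0.107 CPM (-5.38 ± 0.23, adjusted p = 1.474e-07). The granzyme and perforin genes, all 7 of them, were lower in CP1 than in P1 (median -4.07) and higher in CP2 than in P1 (median 3.32), and of the 13 urothelial genes 11 were higher and 1 lower in CP1 than in P1, 6 were lower in CP2 than in P1 and 13 were lower in CP2 than in CP1.

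Some whole chromosomes shifted upward by small amounts, which may reflect gains in the cell lines. Others lay lower and are given last. The chromosomes were picked after their medians were seen, and the tests for a gain by 10 Mb windows with at least 10 genes were written before the windows were seen. Those for chromosomes 6 and 19 and for a loss in P1 were chosen after the values were seen. On chromosome 15 the median log2 fold change of CP1 versus P1 over 490 genes lay 0.39 above that of all genes, and 100% of 9 windows lay above it. On chromosome 18 CP2 versus P1 lay 0.38 above over 300 genes, with 100% of 9 windows. Both are what a gain along the chromosome predicts. A loss in P1 alone would raise both CP lines alike, and is argued against for both chromosomes. CP2 versus P1 lay at -0.05 from all genes on chromosome 15, and CP1 versus P1 at 0.01 on chromosome 18. CP2 versus CP1 lay above in 0% of the 9 windows of chromosome 15 and in 100% of the 9 of chromosome 18. A loss in P1 together with one in the other CP line stays open. On chromosome 8 CP2 versus P1 lay 0.27 above with 84.6% of 13 windows, which decides neither way. CP2 versus CP1 lay 0.38 above there, with 76.9% of the 13 windows. On chromosome 6 CP2 versus P1 lay 0.23 above with 86.7% of 15 windows, which also decides neither way, and CP2 versus CP1 lay 0.26 above with 15 of 15. On chromosome 19 both CP lines lay above P1, CP2 by 0.32 with 100% of 6 windows and CP1 by 0.15 with 5 of 6. CP2 versus CP1 lay 0.20 above there, with 100% of the windows, so a loss in P1 alone is argued against, while one beside a gain in CP2 stays open. Downward shifts were present as well. Chromosome 17 lay at -0.17 from all genes in CP2 versus P1, with 1 of 9 windows above. Chromosome 1 lay at -0.18 in CP2 versus CP1, with 2 of 20 windows above. The 5 Y genes lay at -1.60 in CP1 versus P1 and -1.10 in CP2 versus P1, and were too few for windows. No explanation was tested for these. No DNA was measured.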
